A study of Homo sapiens with 6 samples.

How the data were processed

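Total RNA of T47D cells was extracted with a commercial RNA kit, labelled with biotin and hybridised to Affymetrix expression arrays, per the labels' protocols. The 6 samples were grouped by their titles into 3 parental and 3 palbociclib-resistant samples, each numbered 1 to 3 in the titles. The labels also describe cells grown without the drug again after resistance, which are not analysed here. The series text names the U133 Plus 2.0 array, but the table holds 22215 probe sets and the platform annotation given with it is that of a smaller array of the same family, so genes measured only by the larger array are not analysed here.

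The deposited values are intensities on a linear scale, 1 per probe set and array. Per the submitters' processing notes they were made with RMA, which corrects the background, normalizes between arrays and summarises probes to probe sets. Its version, the software that ran it and the step that returned the values to a linear scale are not given in the sources used here. Intensities ran from 6.34 to 25230, and array medians from 102.5 to 105.0. The sorted log2 values differed between arrays by an SD of at most 0.0412 at any rank, so the arrays had nearly but not exactly equal distributions, which leaves little room to see a shift common to most genes. Background correction compresses changes of dim probe sets, and a fold is on the log2(intensity + 1) scale, which understates changes of low values. No detection calls were used, so a dim gene is not shown to be expressed.

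Probe sets were named through the platform annotation: 19064 had 1 listed gene, 1043 had several and 2108 had none listed. Of the 19064, 19052 were matched by gene identifier to the NCBI table of assembly GRCh38.p14, and 0 symbols changed. That table was used only for names and for which genes neighbour each other, since the sources used here name no genome build. Each of 11963 genes was represented by its probe set with the highest mean over the 6 arrays, among probe sets with 1 listed gene. For 4309 genes there were several probe sets to choose from.

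The following choices were made before the data were examined: the groups, the test, the 29 gene lists, the named genes' rule and the alternatives, except those named as added. The plan foresaw log2 values or, if the table was linear, log2 with a pseudocount of 1; the table was linear, so log2(intensity + 1) was used. Genes were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the group as the sole factor, no filter on dim genes and Benjamini-Hochberg adjustment over all 11963 genes. A gene was called at an adjusted p under 0.05. Errors of log2 changes are limma's moderated standard errors, and errors of intensities are SDs over 3 arrays. The lists, written from textbook knowledge, had 13 to 41 measured members. Each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 29 lists. With a correlation estimated from the data for each list, 0 of the 8 called lists held. The estimate was -0.031 for the cholesterol and fatty acid list and 0.007 for senescence factors, below the preset 0.01. A higher correlation therefore did not end these calls. Their unadjusted camera p still rose, from 0.000108 to 0.0125 for cholesterol and from 0.00023 to 0.0192 for senescence factors. The settings thus differ in more than the correlation. A call lost with the estimate therefore does not by itself show an effect of correlation. In the other called lists the estimate was 0.019 to 0.611, highest for replication. Some lists share members, such as CCND1 in the G1 and the estrogen receptor lists. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

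Named genes were chosen by rule: the 10 largest rises and 10 largest falls among called genes whose 3 values in one group all lay above those of the other, with a mean log2 value of at least 6 in the higher group and a symbol that is no clone or reading frame code, then 17 genes of the CDK4/6, TGF-β and estrogen receptor pathways whatever their change, then up to 2 called members with the largest rise and 2 with the largest fall of each list, or the member with the lowest p where none was called. No named gene had probe sets called in opposite directions. The probe sets used for 7 named genes (VCX2, HDGFL3, SPDEF, FN1, HLA-DRB1, RPL31 and AKR1C2) are of a design that can also match transcripts of other genes, as shown by the x in their names.

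Arrays with the same repeat number deviated together: the correlation of their deviations from the group means, over all genes, was 0.307, 0.185 and 0.257 for repeats 1, 2 and 3, and each array correlated best with its own number. The numbers were therefore taken to pair the samples. This pairing comes from the data, since the labels do not say that a number marks a shared culture or day. The fit without a block, fixed beforehand, remained the main one, and the fit with the repeat number as a replicate block was an alternative.

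Other alternatives were quantile normalization, median centring, filters at the median and at the 30th percentile of mean intensity, the mean of all probe sets of a gene, a test per probe set, an intensity trend with a robust prior, array weights, limma's treat against a log2 change of 0.5, camera on ranks, fry, and each array left out in turn. Pseudocounts of 0 and 16, the estimated correlation within the blocked fit, and leaving out both arrays of a repeat number were added after the data were seen.

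The tests were checked on simulated data for the same comparison of 3 against 3 arrays, with 11963 genes of which 200 were changed. The test recovered 92.5% of genes changed by 0.5 on the log2 scale (62 of 67), and 100% of those changed by 1 (67 of 67) and by 2 (66 of 66). It made 12 false calls, 5.8% of its calls. In 20 simulations without any change, 0 lists and 2 genes were called in all, and a list moved on purpose was called with 0 others. The simulated genes varied independently of each other. These simulations therefore cannot show how often camera falsely calls lists of correlated genes, such as replication (estimated correlation 0.611) or interferon (0.396).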

Results

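Gene expression was measured on Affymetrix oligonucleotide arrays in 6 RNA samples of T47D, an established estrogen receptor-positive line of luminal breast cancer. Parental cells gave 3 samples. Cells cultured to resistance against palbociclib, an inhibitor of the cyclin-dependent kinases CDK4 and CDK6, gave the other 3. The medium of resistant cells held 100 nM of the drug and that of parental cells none, so the comparison covers resistance and drug exposure together. Median intensities of the 6 arrays lay between 102.5 and 105.0, lower quartiles between 29.1 and 30.3, and upper quartiles between 468.7 and 476.8. Across 11963 genes, which are not independent replicates, Pearson correlations were 0.9972 to 0.9985 between arrays of a group and 0.9896 to 0.9909 between arrays of different groups. The first principal component held 73.8% of the variance and separated the groups, with parental arrays at -18.12 to -17.16 and resistant arrays at 17.15 to 18.5. The second held 10.8% and set repeat 3 apart in both groups. Repeat 3 lay at -11.12 in parental and -7.25 in resistant cells, and the other arrays at 1.44 to 6.51. The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

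The comparison of resistant with parental cells asks which transcripts differed once the cells grew in the drug, and the series names suppression of the TGF-β pathway by microRNAs as its subject. The largest rise was that of TWIST1, a transcription factor of mesenchymal development, at 3.66 ± 0.11 on the log2 scale (SE, 3 arrays per group). Its mean intensity went from 38.7 ± 6.08 (SD, n = 3) in parental to 496 ± 9.28 (SD, n = 3) in resistant cells, a 12.6-fold difference on the log2(intensity + 1) scale used for all folds. HEY2, a transcriptional repressor downstream of Notch, rose 6.71-fold. SDC2, a heparan sulfate proteoglycan of the cell surface, rose 4.5-fold, from an intensity of 244 to 1100. CHST15, a chondroitin sulfate sulfotransferase, rose 4.33-fold. The other rises among the 10 largest were those of TRIM58, a ubiquitin ligase (8.62-fold), HEPH, a copper-dependent ferroxidase (8.15-fold), VCX2 (7.51-fold), SLC1A1, a glutamate transporter (7.15-fold), DHRS2, a short-chain dehydrogenase (5.88-fold), and HDGFL3 (4.64-fold). Both probe sets of VCX2 can also match its X-linked paralogs, so the gene behind that signal is uncertain. The parental intensities of TRIM58 (12.7), HEPH (17.3) and SLC1A1 (11.4) lay below the lower quartile of every array, so their folds and ranks depend on values near the floor.

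The largest fall was that of CALCR, the calcitonin receptor, at -5.24 ± 0.16 on the log2 scale (SE), from an intensity of 1070 ± 85.9 to 27.9 ± 7.47 (SD, n = 3 each), the latter below the lower quartile of every array. DMD, which encodes dystrophin, fell by 4.24 on the log2 scale, from an intensity of 640 to 33. NR2F1, an orphan nuclear receptor, fell by 3.95, from 935 to 60.8. CLDN1, a tight junction protein, fell by 3.71, from 2300 to 175, and had the lowest adjusted p of all genes (4.44e-09, limma with Benjamini-Hochberg adjustment). OLR1, a receptor for oxidised lipoprotein, fell by 3.64. SULF1, an extracellular sulfatase of heparan sulfate, fell by 3.34. The secreted products adrenomedullin (ADM), corticotropin-releasing hormone (CRH) and lipocalin (LCN2) also fell, with log2 changes of -3.15, -2.73 and -2.58, and the protease inhibitor SERPINE2 dropped by 2.5, to an intensity of 22.4, also below the lower quartile of every array. These 20 changes had adjusted p of at most 0.000128. Averaging all probe sets of a gene moved 6 of them by over 1.5 times, to a log2 change of 1.49 for HEPH, 1.45 for SLC1A1, 1.76 for DHRS2, -2.82 for CALCR, -2.03 for DMD and -1.85 for CRH, and a pseudocount of 16 gave 2.22 for TRIM58, 2.3 for HEPH, 1.91 for SLC1A1, -4.64 for CALCR and -1.94 for SERPINE2. The second probe set of HEPH (-0.06 ± 0.09) and that of SLC1A1 (0.06 ± 0.13) showed no such change. Both were near the floor in parental and resistant cells, at intensities of 11 and 10.5 for HEPH and 17.1 and 17.9 for SLC1A1. They therefore cannot speak for or against the rises, and the lower means of these 2 genes reflect them.

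In total 2551 of 11963 genes (21.3%) passed an adjusted p of 0.05, 1347 higher and 1204 lower in resistant cells, with a median absolute log2 change of 0.393. A log2 change of at least 1 was reached by 223 of them, 123 higher and 100 lower. The 3 values of one group lay entirely above those of the other for 4450 genes (37.2%), where chance gives 10%. Neighbouring genes often moved together: windows of 25 neighbouring genes with an absolute median log2 change above 0.15 numbered 538 of 11378, against at most 44 in 100 shuffled gene orders. Of the called genes named here, 24 lay in stretches made of such windows. Those that moved with their stretch were RB1, BMP4, NR2F1, PIK3R1, TUT4 and ATP5PO in lowered stretches, and HEPH, SLC1A1, VLDLR, CDK6, ASNS, DROSHA, FOXO3, SESN1, INHBB, ITGA6, SC5D, SPDEF, TTK and VIM in raised ones. CALCR, DMD, SERPINE2 and CTSL moved against theirs.

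**Figure D1:**
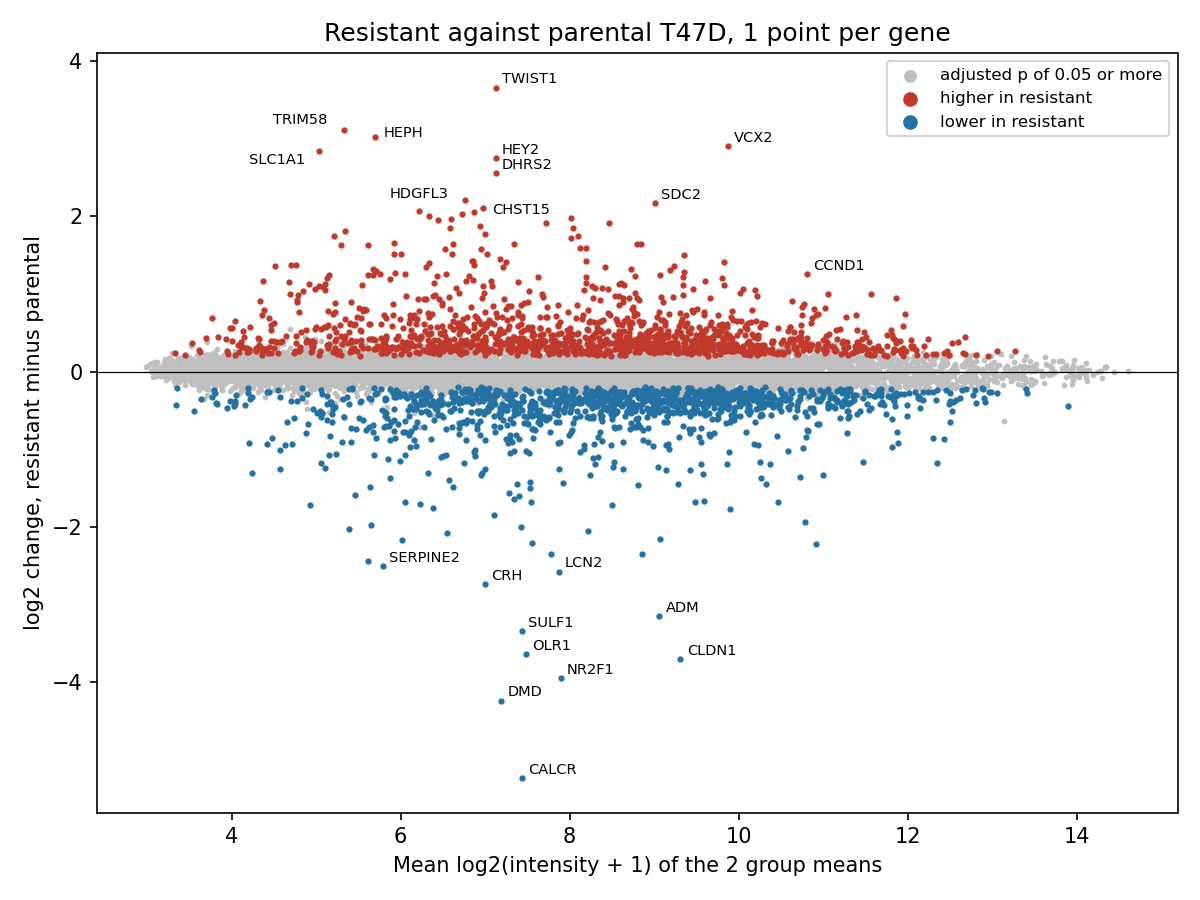
Log2 change of resistant against parental cells (y axis) against the mean log2(intensity + 1) of the group means (x axis), 1 point per gene for 11963 genes, with genes past an adjusted p of 0.05 in red (higher, 1347) or blue (lower, 1204) and the rest in grey. The 10 largest rises and falls and CCND1 are named, from TWIST1 at 3.66 to CALCR at -5.24.

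Among the genes of the drug's own pathway, CCND1, which encodes cyclin D1, the activating partner of CDK4 and CDK6, rose by 1.26 ± 0.14 on the log2 scale (2.4-fold, from an intensity of 1170 to 2790, adjusted p = 0.000155). CDKN1A, which encodes the CDK inhibitor p21, fell by 0.91 ± 0.08 (adjusted p = 3.02e-05). RB1, the pocket protein that CDK4 and CDK6 phosphorylate, fell by 0.63 ± 0.09, from an intensity of 1200 to 775 (adjusted p = 0.000679). RB1 lay in a stretch of 113 neighbouring genes from ATP12A to OR7E156P, of which 38 were called lower and 5 higher. CDK6 rose by 0.31 ± 0.09, from an intensity of 18.5 to 23.2, both below the lower quartile of every array (adjusted p = 0.0283). CDK2 fell by 0.29 ± 0.08 (adjusted p = 0.0248) and CCNE2, a cyclin E gene, by 0.46 ± 0.12 (adjusted p = 0.0234). CDK4 (-0.2 ± 0.12, adjusted p = 0.273) and CCNE1 (0.02 ± 0.1, adjusted p = 0.91) did not pass. Of the 36 measured G1 cyclins, CDKs, RB family members, E2Fs and CDK inhibitors, 2 rose and 12 fell (2 and 13 adjusted over the list alone), E2F8, a repressor E2F, among the latter at -0.9 ± 0.14. The list shifted downward by limma's camera (median log2 change -0.086, adjusted p = 0.00576 with a preset correlation), and had adjusted p = 0.403 with an estimated correlation. The test fry, which asks whether a list's own genes move one way, called it downward (adjusted p = 0.0262). The call of CDK6 was lost without parental replicate 2 or 3 or resistant replicate 1 or 2 (adjusted p up to 0.104) and with a pseudocount of 16 (0.0585), that of CDK2 without parental replicate 1 or 2 or resistant replicate 1 or 3 (up to 0.0994) and with the mean of its probe sets (0.0561), and that of CCNE2 without parental replicate 1 or 2 (up to 0.0824). Of the other probe sets of CDK2, 1 fell by 0.52 ± 0.12 (adjusted p = 0.0158 over all probe sets). The remaining one (0.08 ± 0.07) was dim, at intensities of 28.4 in parental and 30.1 in resistant cells. Without parental replicate 3, CDK4 was called lower (adjusted p = 0.0198).

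**Figure D2:**
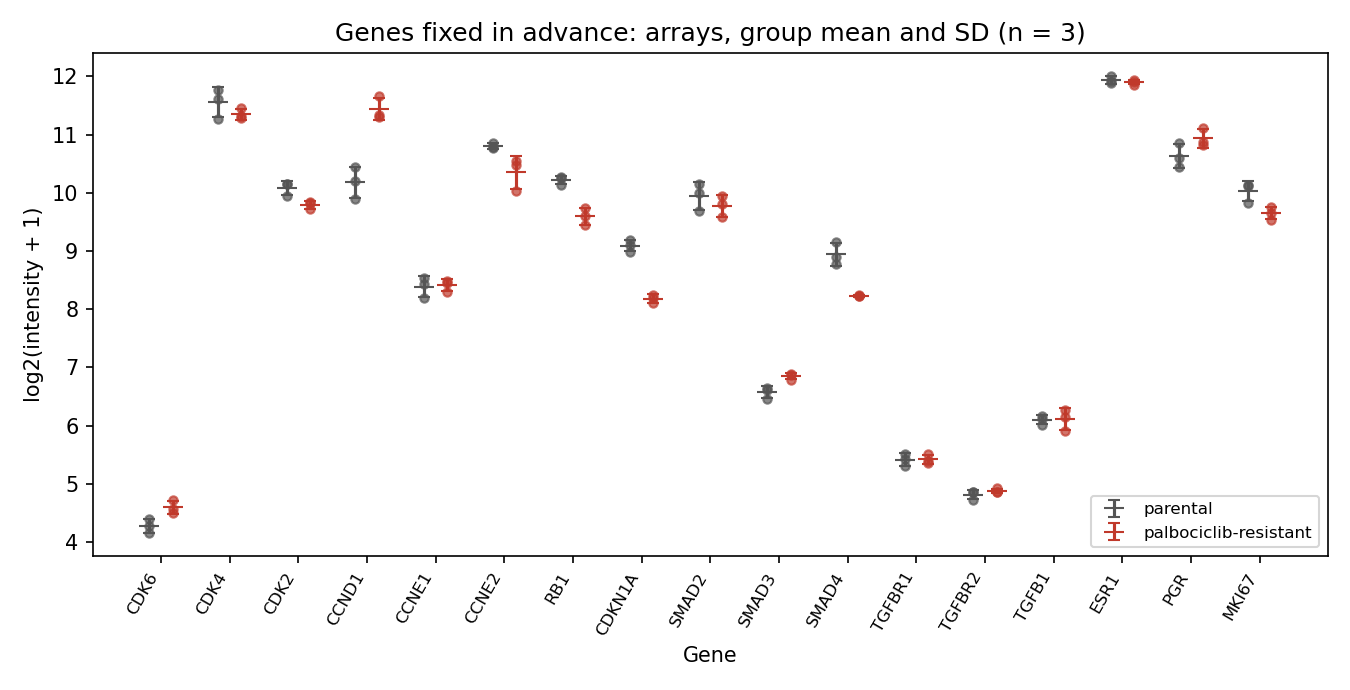
Log2(intensity + 1) of the 17 genes fixed in advance (y axis, 1 gene per position on the x axis) in parental (grey) and resistant (red) cells, with a point per array, the group mean as a horizontal bar and the SD as error bars (n = 3 per group). The 3 resistant arrays lie above the parental ones for CCND1, CDK6 and SMAD3 and below them for RB1, CDKN1A, SMAD4, CDK2, CCNE2 and MKI67.

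The called genes of DNA replication, which these kinases drive through E2F, were all lower in resistant cells, and those of mitosis nearly all. Across all 11963 genes 21.3% were called, 1347 higher and 1204 lower. Of 39 measured replication genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone), including thymidylate synthase (TYMS, -0.61 ± 0.08) and the ribonucleotide reductase subunit RRM2 (-0.51 ± 0.08). Of 41 genes of G2/M and mitosis, 8 fell and 1 rose (10 and 2 adjusted over the list alone, and 11 and 3 with the replicate block). CDC20, an activator of the anaphase-promoting complex, fell by 1.04 ± 0.16 and the transcription factor MYBL2 by 0.51 ± 0.11, while the spindle checkpoint kinase TTK rose by 0.33 ± 0.08. The median log2 change was -0.098 for replication (camera adjusted p = 0.00225) and -0.134 for mitosis (0.00168). With an estimated correlation the replication list had adjusted p = 0.804 and the mitosis list adjusted p = 0.633. The mean log2 value of the replication list was 10.21, 10.204 and 9.98 in parental replicates 1, 2 and 3 and 10.034, 10.026 and 9.924 in the resistant ones, so the groups overlapped while the resistant array was lower within each number. With the replicate block its camera adjusted p was 0.00184, or 0.67 with an estimated correlation. The self-contained directional test, fry, gave adjusted p of 0.304 and 0.14, and the mitosis list also lost its call without resistant replicate 3 (adjusted p = 0.0623). MKI67, the proliferation marker Ki-67, fell by 0.37 ± 0.1 (adjusted p = 0.0222), a call lost without parental replicate 1 or 2 or resistant replicate 2 or 3 (adjusted p up to 0.0904), and TTK lost its call without replicate 1 or 2 of either group (up to 0.073). Of 13 histone genes transcribed in S phase, 2 rose and 0 fell (2 and 0 adjusted over the list alone), H2AC6 (0.77 ± 0.19) and H2AC8 (0.72 ± 0.12), and the list did not shift (median 0.034, adjusted p = 0.512, or 0.222 and 0.302 among genes above the median intensity). The call of H2AC6 was lost without parental replicate 1 or 2 or resistant replicate 3 (adjusted p up to 0.0777).

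TGF-β signalling genes moved in both directions. Of 35 measured ligands, receptors and SMADs of the TGF-β and BMP families, 7 rose and 6 fell (10 and 6 adjusted over the list alone). The title of the series names this pathway, so the choice of the list is not independent of the study. TGFBR3, the co-receptor betaglycan, had the largest fall at -2.06 ± 0.1 (4.16-fold, from an intensity of 611 to 145, adjusted p = 6.74e-07), and the ligand BMP4 fell by 0.73 ± 0.08. SMAD4, the shared partner of the receptor-regulated SMADs, fell by 0.71 ± 0.1 (adjusted p = 0.000621), while its second, dimmer probe set gave -0.27 ± 0.08 (adjusted p = 0.0586 over all probe sets). INHBB, an activin and inhibin subunit, rose by 0.57 ± 0.09 and SMAD1, a SMAD of BMP signalling, by 0.48 ± 0.07. SMAD3 rose by 0.28 ± 0.07 (adjusted p = 0.0246), a call lost with the mean of its probe sets (0.12, adjusted p = 0.224) and without parental replicate 3 or resistant replicate 2 or 3 (adjusted p up to 0.082). The receptors TGFBR1 (0 ± 0.08) and TGFBR2 (0.07 ± 0.07), the ligand TGFB1 (0.01 ± 0.1) and SMAD2 (-0.18 ± 0.13) did not pass. TGFBR2 had intensities of 27.2 in parental and 28.5 in resistant cells, below the lower quartile of every array. TGFBR1 was also dim, at 41.7 and 41.8, so a change of either receptor could be missed. TGFB1 had intensities of 67.6 and 68.3, below the median of every array. Its second, dimmer probe set gave -0.37 ± 0.12 (limma, adjusted p = 0.0754 over all probe sets), so a change of TGFB1 could be missed too. The list as a whole did not shift (median 0.026, mean -0.054, test direction upward, adjusted p = 0.99).

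Of 29 measured genes listed as induced by TGF-β, 5 rose and 7 fell (6 and 9 adjusted over the list alone). Their response to TGF-β in T47D was not measured here, so the direction of a member does not report the pathway's activity. ID3, an inhibitor of basic helix-loop-helix factors, fell by 1.27 ± 0.11 and ACTA2, smooth muscle actin, by 1.05 ± 0.09. The actin-binding protein TAGLN rose by 0.62 ± 0.06 and the small GTPase RHOB by 0.61 ± 0.07. The median log2 change was -0.042 and the list did not shift (camera adjusted p = 0.454), nor did it among genes above the median intensity, at a median of -0.253 (adjusted p = 0.371). Of 16 measured genes of microRNA processing and silencing, 1 rose and 1 fell (1 and 1 adjusted over the list alone). DROSHA, the nuclease that cuts primary microRNA transcripts, rose by 0.63 ± 0.07 (adjusted p = 0.000115), in a raised stretch of 70 neighbouring genes from SDHA to TTC33, and TUT4, a uridylyltransferase of microRNA precursors, fell by 0.39 ± 0.09 (adjusted p = 0.0128, or 0.0524 with the mean of its probe sets). The second probe set of TUT4 was near the floor, at intensities of 14.5 in parental and 13.8 in resistant cells. The microRNA list did not shift (median -0.088, adjusted p = 0.512). Of 28 genes of extracellular vesicle formation and release, 4 rose and 4 fell (6 and 4 adjusted over the list alone), with CD9 (0.75 ± 0.11) and SDC1 (0.56 ± 0.08) higher and FLOT2 (-0.45 ± 0.07) and CD63 (-0.38 ± 0.07) lower, and no shift of the list (median 0.051, adjusted p = 0.89, or 0.08 and 0.749 among genes above the median intensity).

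Most measured genes of the type I interferon response fell in resistant cells. Of its 37 measured genes, 25 fell and 1 rose (31 and 1 adjusted over the list alone), with a median log2 change of -0.543 (camera adjusted p = 1.08e-13, the lowest of the 29 lists). With an estimated correlation the list had adjusted p = 0.453, while fry called it downward (adjusted p = 0.0186). The antiviral GTPase MX1 fell by 1.77 ± 0.15, from an intensity of 1760 to 526, and IFIT5, an RNA-binding antiviral protein, fell by 1.69 ± 0.12. HERC5, a ligase for the ubiquitin-like protein ISG15, rose by 1.19 ± 0.11. Among genes above the median intensity the list's median was -1.197. Leukocyte markers, which would report white blood cells in a culture, included 1 rise and 0 falls among 22 measured genes (1 and 0 adjusted over the list alone), that of CD8A (0.52 ± 0.1), and had a median log2 change of 0.008 (adjusted p = 0.89). They were dim in parental cells already, at a median log2 value of 5.25.

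Of 23 measured genes of MHC and antigen presentation, 3 rose and 6 fell (3 and 6 adjusted over the list alone). The class II genes HLA-DRB1 (1.07 ± 0.06) and HLA-DMA (0.95 ± 0.07) rose, while the immunoproteasome subunits PSMB8 (-0.51 ± 0.1) and PSMB9 (-0.42 ± 0.11) fell. The HLA-DRB1 probe set can also match paralogous DRB genes, and the call of PSMB9 was lost without parental replicate 1 or 3 or resistant replicate 3 (adjusted p up to 0.0684). That list did not shift (median -0.095, adjusted p = 0.324, or -0.007 and 0.987 among genes above the median intensity). Of 24 measured inflammatory and secretory factors of senescence, 10 fell and 0 rose (11 and 0 adjusted over the list alone), the chemokines CCL20 (-1.44 ± 0.24) and CCL2 (-1.13 ± 0.11) the most. Their median log2 change was -0.211 (camera adjusted p = 0.00167), with adjusted p = 0.197 with an estimated correlation and adjusted p = 0.189 among genes above the median intensity, where the median log2 change was -0.39. Fry called these factors downward (adjusted p = 0.00403).

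**Figure D3:**
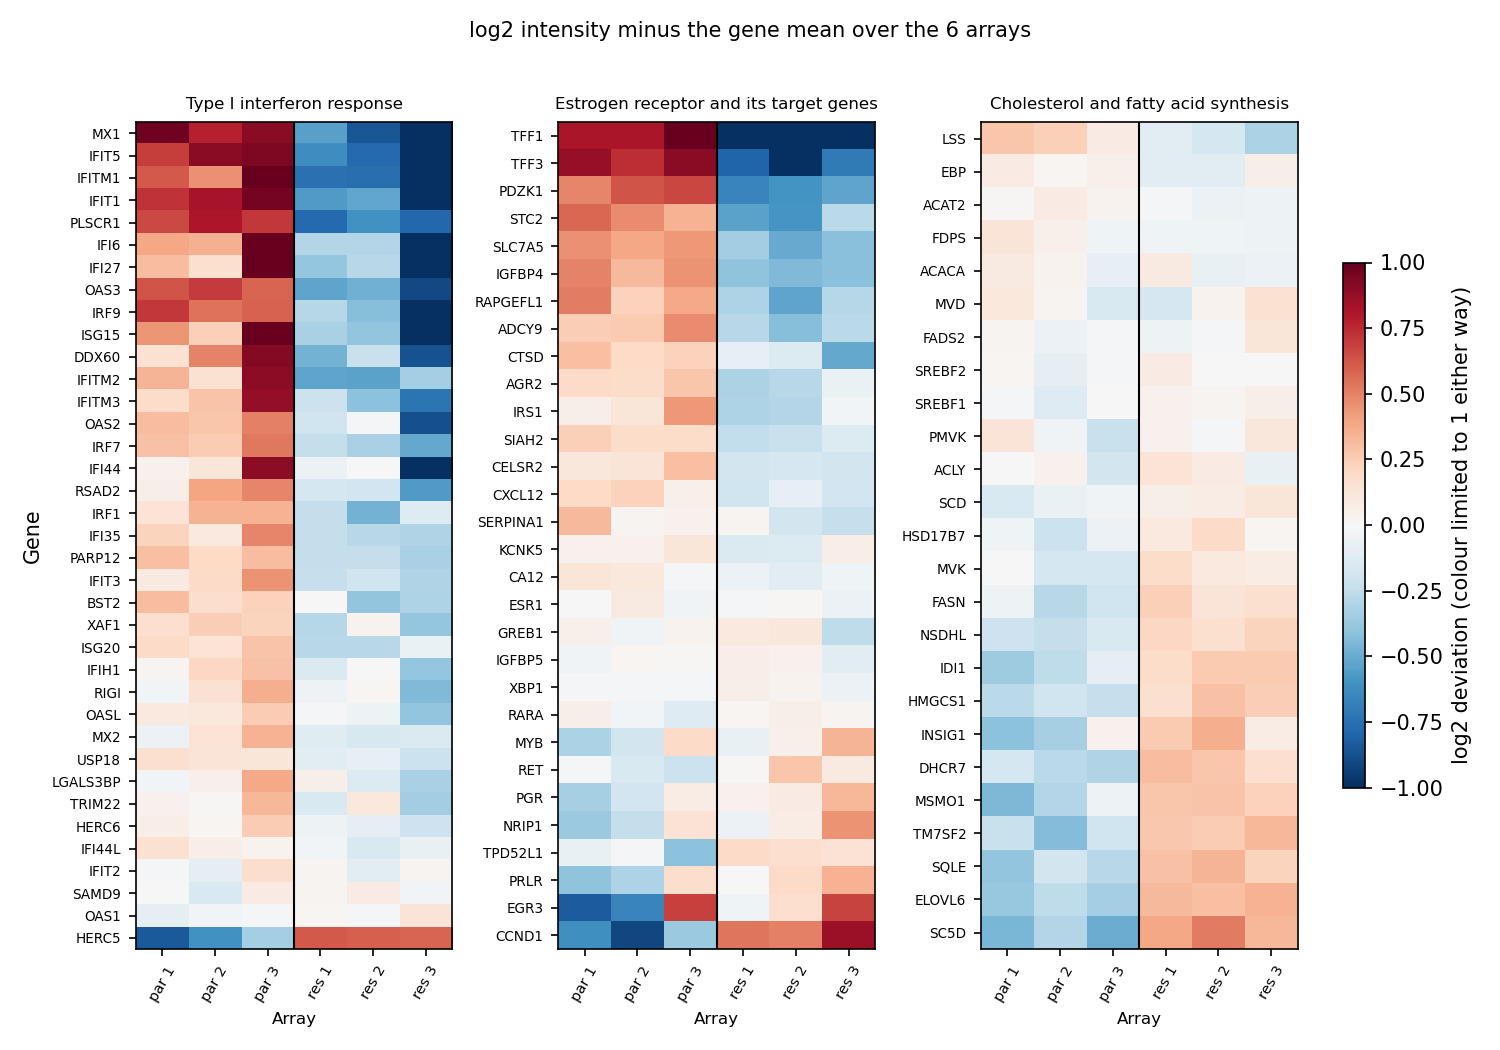
Log2 intensity of each measured member of the interferon, estrogen receptor and cholesterol lists minus its mean over the 6 arrays (colour, limited to 1 either way), with 1 row per gene and 1 column per array, parental left and resistant right of the black line. Of the 37 interferon genes 25 were called lower in resistant cells, and of the 25 cholesterol and fatty acid genes 12 were called higher.

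ESR1, which encodes the estrogen receptor, did not pass (-0.04 ± 0.07, adjusted p = 0.744), with intensities of 3930 in parental and 3820 in resistant cells. Among 30 measured genes of the receptor and its targets, 14 fell and 2 rose (15 and 4 adjusted over the list alone, and 15 and 7 with the replicate block). The secreted trefoil factors TFF1 and TFF3 fell by 2.35 ± 0.24 and 1.68 ± 0.09, and CCND1 (1.26 ± 0.14) and TPD52L1 (0.34 ± 0.1) rose. PGR, the progesterone receptor, changed by 0.3 ± 0.11 and did not pass (adjusted p = 0.0889), but did with the replicate block (adjusted p = 0.0104), array weights (0.0469) and without parental replicate 3 (0.0179). The list shifted downward (median -0.201, camera adjusted p = 0.000655), and had adjusted p = 0.197 with an estimated correlation. It was also called downward by fry (adjusted p = 0.00403). The call of TPD52L1 was lost on leaving out any 1 array except parental replicate 2 (adjusted p up to 0.102) and with the mean of its probe sets (0.0899).

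Of 24 luminal epithelial genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone), the receptor tyrosine kinase ERBB2 by 0.55 ± 0.08 and the transcription factor SPDEF by 0.51 ± 0.09 upward, and ELF5, a factor of luminal progenitors, by -0.54 ± 0.11. Of 19 basal and squamous genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone). The integrin subunit ITGA6 (0.51 ± 0.08) and the oxytocin receptor OXTR (0.41 ± 0.11) rose, and ANXA1 (-0.72 ± 0.08) and EGFR (-0.66 ± 0.07) fell. The other 5 probe sets of EGFR did not pass, the mean of all 6 gave -0.09 (adjusted p = 0.356), and OXTR lost its call without parental replicate 2 or 3 or resistant replicate 1 or 2 (adjusted p up to 0.0903). Among 27 mesenchymal and fibroblast genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone), with TWIST1 and the intermediate filament gene VIM (0.69 ± 0.08) higher and FN1, fibronectin (-0.53 ± 0.12), and S100A4 (-0.5 ± 0.11) lower. Of 13 endothelial markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone), ENG (0.37 ± 0.09) and EGFL7 (0.36 ± 0.08). ENG lost its call without parental replicate 1 or 2 or resistant replicate 3 (adjusted p up to 0.0707). By camera none of these 4 lists shifted, with median log2 changes of 0.078 (luminal, adjusted p = 0.442), -0.053 (basal, 0.324), 0.03 (mesenchymal, 0.512) and -0.005 (endothelial, 0.89, with a mean of 0.044 and an upward test direction). The self-contained test fry called the luminal (adjusted p = 0.00632) and mesenchymal lists (0.0277) upward and the basal list (0.0277) downward.

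Lipid synthesis genes that passed were mostly higher in resistant cells. Of 25 measured genes of cholesterol and fatty acid synthesis, 12 rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 change of 0.209 (camera adjusted p = 0.00104). With an estimated correlation the list had adjusted p = 0.197, while fry called it upward (adjusted p = 0.000354). SC5D, a sterol desaturase, rose by 0.83 ± 0.08 and the fatty acid elongase ELOVL6 by 0.65 ± 0.07. LSS, lanosterol synthase, fell by 0.4 ± 0.08. Of 27 genes of hypoxia and glycolysis, 4 rose and 7 fell (5 and 10 adjusted over the list alone). ADM and the prolyl hydroxylase EGLN3 (-0.91 ± 0.14) fell, and the glycolytic genes HK2 (0.77 ± 0.08) and PFKFB3 (0.44 ± 0.11) rose. This list shifted downward by a small margin (median -0.113, camera adjusted p = 0.038) and had adjusted p = 0.591 with an estimated correlation. Its call was also lost with the replicate block (adjusted p = 0.0831), quantile normalization (0.0833), ranks (0.0871), filters on dim genes (0.302 above the median intensity, at a median log2 change of -0.104, and 0.303 above its 30th percentile), and without parental replicate 3 (0.0955) or resistant replicate 2 (0.109). Fry called the hypoxia and glycolysis list downward (adjusted p = 0.0168). PFKFB3 lost its own call without parental replicate 1 or 2 or resistant replicate 3 (adjusted p up to 0.0717).

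Of 36 genes of oxidative phosphorylation, 3 rose and 2 fell (2 and 2 adjusted over the list alone), with NDUFB3 (0.32 ± 0.06) and COX5B (0.24 ± 0.07) higher and CYC1 (-0.29 ± 0.07) and ATP5PO (-0.23 ± 0.06) lower, and the list did not shift (median -0.006, mean 0.006, test direction downward, adjusted p = 0.89). The call of ATP5PO was lost on leaving out any 1 of the 6 arrays (adjusted p up to 0.0785), that of COX5B on leaving out any but parental replicate 3 (up to 0.117), and that of CYC1 without replicate 1 of either group (up to 0.0574). Of 33 cytosolic ribosomal protein genes, 0 rose and 0 fell in limma's test, also adjusted over the list alone and with the replicate block. The lowest p belonged to RPL31 (0.14 ± 0.06, unadjusted p = 0.0489, adjusted p = 0.149). It was called higher with the mean of its probe sets (adjusted p = 0.0137) and with an intensity trend and robust prior together (0.0154). The list's median was 0.006 (adjusted p = 0.94).

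Growth factor and PI3K signalling genes changed in both directions. Of 37 growth factor receptors, ligands and MAPK feedback genes, 8 rose and 5 fell (10 and 5 adjusted over the list alone), with FGFR4 (0.7 ± 0.08) and ERBB2 higher and ERBB4 (-1.17 ± 0.08) and PHLDA1 (-1.16 ± 0.07) lower. Of 21 genes of the PI3K, AKT and mTOR pathway, 5 rose and 4 fell (5 and 4 adjusted over the list alone). DEPTOR, an inhibitor of mTOR, rose by 1.41 ± 0.09, from an intensity of 560 to 1480 (adjusted p = 5.47e-06), and the transcription factor FOXO3 by 0.64 ± 0.08, while the regulatory subunit PIK3R1 fell by 0.54 ± 0.08 and the adaptor IRS1 by 0.41 ± 0.11. IRS1 lost its call without parental replicate 3 or resistant replicate 1 or 2 (adjusted p up to 0.088). Of 28 genes of the Wnt, Notch and Hippo pathways, 5 rose and 9 fell (7 and 10 adjusted over the list alone), with HEY2 and the ligand WNT5A (1.05 ± 0.1, from a dim intensity of 23 to 48.9) higher and the Wnt antagonist DKK1 (-0.97 ± 0.14) and the coactivator WWTR1 (-0.65 ± 0.1) lower. By camera none of the lists shifted, at medians of 0.018 (growth factors, mean -0.01, test direction upward, adjusted p = 0.958), 0.04 (PI3K, 0.697) and -0.096 (Wnt, mean 0.026, test direction downward, 0.443). The PI3K list was called upward by fry (adjusted p = 0.0277).

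The 5 remaining lists of stress, death, degradation and drug handling did not shift by camera, while fry called 3 of them downward, p53 targets (adjusted p = 0.0186), the unfolded protein and stress responses (0.0343) and drug handling (0.00833). Among 21 p53 targets, 4 rose and 4 fell (4 and 5 adjusted over the list alone), SESN1 (0.61 ± 0.09) and TIGAR (0.57 ± 0.07) upward and the death receptor FAS (-1.03 ± 0.07) and CDKN1A downward (list median -0.085, adjusted p = 0.324). Among 22 apoptosis regulators, 3 rose and 2 fell (3 and 2 adjusted over the list alone), CASP8 (0.6 ± 0.11) and BIK (0.56 ± 0.08) upward and BAX (-0.49 ± 0.13) and BCL2L2 (-0.29 ± 0.06) downward (median -0.027, mean 0.018, test direction upward, adjusted p = 0.99). BAX lost its call without parental replicate 1 or resistant replicate 2 or 3 (adjusted p up to 0.0948). Among 27 genes of the unfolded protein and integrated stress responses, 5 rose and 4 fell (5 and 5 adjusted over the list alone), VLDLR (0.93 ± 0.17, from a dim intensity of 19.1 to 37.4) and asparagine synthetase (ASNS, 0.66 ± 0.07) upward and CEBPB (-0.6 ± 0.06) and TRIB3 (-0.32 ± 0.07) downward (median -0.083, adjusted p = 0.367). Among 35 lysosome and autophagy genes, 5 rose and 4 fell (7 and 5 adjusted over the list alone), the cathepsins CTSH (0.97 ± 0.13) and CTSL (0.53 ± 0.08) upward and the peptidases TPP1 (-0.73 ± 0.07) and CTSD (-0.48 ± 0.11) downward (median 0.035, adjusted p = 0.697). Among 27 drug transporters and metabolic enzymes, 3 rose and 6 fell (4 and 9 adjusted over the list alone), CYP1A1 (0.97 ± 0.07) and the transporter ABCC5 (0.52 ± 0.07) upward and ALDH1A3 (-1.57 ± 0.19) and AKR1C2 (-0.78 ± 0.08) downward (median -0.048, adjusted p = 0.324, or -0.088 and 0.699 among genes above the median intensity). The AKR1C2 probe set can also match related AKR1C genes.

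**Figure D4:**
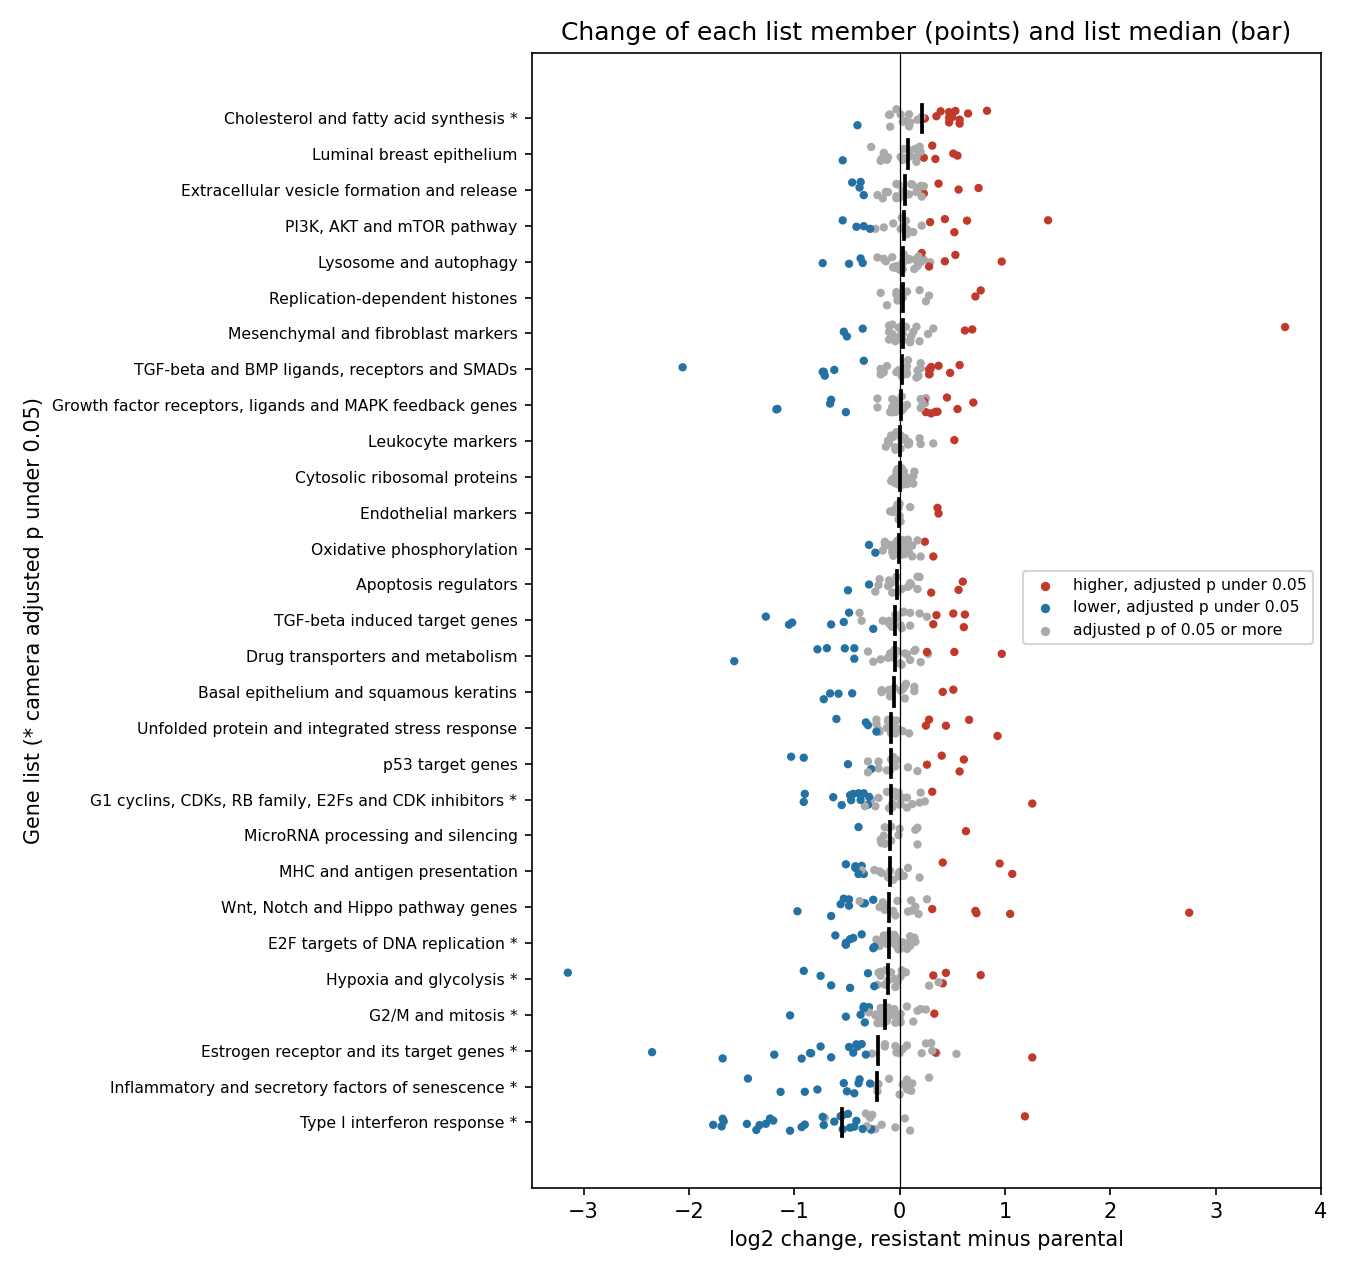
Log2 change of each measured member (points, x axis) of the 29 gene lists (y axis), in red where called higher, blue where called lower and grey otherwise, with the list median as a black bar and an asterisk where camera's adjusted p with a preset correlation was below 0.05. The medians run from -0.543 for the interferon response to 0.209 for cholesterol and fatty acid synthesis.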

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

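Signal from probe sets with no single listed gene was left out of the comparisons above and differed between the groups. Of 3151 such probe sets, 193 were called higher and 192 lower in the resistant arrays (limma, adjusted p under 0.05), 14 and 10 of them by at least 1 on the log2 scale. The largest rise was 2.88 and the largest fall -2.5. They are reported because they lie outside the main measurement and, for the 193 higher ones, exceed the level in the parental samples, and no explanation was tested. No formal test of single outlying arrays was made in groups of 3, but each array was left out in turn, as given below.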

How the results depend on the processing

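Alternatives with other pseudocounts, with the blocked fit and an estimated correlation together, and without both arrays of a repeat number were chosen after seeing the data. The count of 2551 calls was 1085 to 2493 with arrays left out, and fell by over 1.5 times only without both arrays of repeat 1 (1216) or repeat 2 (1085). Without both arrays of repeat 3, which also leaves 2 arrays per group, it was 2342. Repeat 3 was the array farthest from the others of its group. The SD of log2 differences was 0.139 between parental arrays 1 and 2 and 0.144 between resistant arrays 1 and 2. For pairs of a group that include repeat 3 it was 0.169 to 0.189. Leaving out repeat 3 thus kept the closer arrays, which goes with the higher count, and no further test of the cause was made. Other settings tested per gene gave 2127 to 3116, the last with the replicate block, which shared 2520 of the 2551. Among genes above the median intensity, 104 of the called genes changed by at least 1, against 223, since fewer genes were tested. The share of higher calls stayed between 50% and 53.5% over the settings per gene. Of the 115 called named genes, 98 kept their call with each single array left out and 17 lost it at least once. Over the 9 settings with 1 array or both arrays of a repeat number left out, named genes lost a call 117 times in all. Some of the 98 lost theirs without both arrays of a repeat number. Signal over background limits dim genes such as CDK6.

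For lists, values are camera adjusted p unless stated, and for changes not explained by fewer genes or arrays the cause was not tested. The replicate block ended the call of hypoxia (0.0831) and turned the uncalled apoptosis list (0.875), and gave PGR a call; it changed no other call among the lists, fixed genes and named genes. With an estimated correlation all 8 called lists missed the threshold: G1 cyclins 0.403, replication 0.804, mitosis 0.633, estrogen receptor, senescence factors and cholesterol 0.197 each, interferon 0.453 and hypoxia 0.591. In the blocked fit with an estimated correlation, G1 cyclins, replication, mitosis, interferon and hypoxia had 0.67, estrogen receptor, senescence factors and cholesterol 0.654, and apoptosis turned (0.953). Quantile normalization turned leukocyte and endothelial markers (0.985 each), growth factors (0.993) and oxidative phosphorylation (0.668) and ended hypoxia (0.0833). The filter at the median turned TGF-β and BMP genes (0.749) and oxidative phosphorylation (0.987) and ended senescence factors (0.189, with a median log2 change of -0.39 against -0.211) and hypoxia (0.302, with -0.104 against -0.113). The filter at the 30th percentile turned leukocyte markers (0.937) and ended hypoxia (0.303). The mean of all probe sets turned TGF-β and BMP genes (0.932) and apoptosis (0.591). The former also turned with an intensity trend and robust prior together (0.998) and with array weights (0.924). On ranks, endothelial markers (0.986) and apoptosis (0.977) turned and hypoxia was lost (0.0871).

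The test fry asks whether a list's own genes move one way. Of the 8 lists called by camera, replication (0.304) and mitosis (0.14) missed its threshold. Cholesterol (0.000354) passed it upward. Estrogen receptor and senescence factors (0.00403 each), hypoxia (0.0168), interferon (0.0186) and G1 cyclins (0.0262) passed it downward, as by camera. Lists past it but not past camera's were luminal (0.00632), drug handling (0.00833), p53 (0.0186), basal, mesenchymal and PI3K (0.0277 each) and the unfolded protein response (0.0343), and those of opposite sign were TGF-β and BMP (0.456), growth factors (0.547), oxidative phosphorylation (0.887) and Wnt (0.231). With arrays or pairs left out, adjusted p ranged over 0.00031 to 0.0623 for mitosis (lost without resistant replicate 3), 0.0295 to 0.109 for hypoxia, 0.0388 to 0.942 for histones (called without both arrays of repeat 3), 0.794 to 0.966 for TGF-β and BMP, 0.601 to 0.945 for endothelial, 0.852 to 0.946 for growth factors, 0.608 to 0.945 for oxidative phosphorylation, 0.86 to 0.999 for ribosomal and 0.852 to 0.944 for apoptosis. Uncalled genes near 0 changed sign: the log2 change of TGFBR1 was -0.02 with quantile normalization and -0.01 with median centring, that of TGFB1 -0.01, 0 and, with the mean of its probe sets, -0.18, and that of ESR1 0.01 with the mean of its probe sets. With arrays left out they were -0.05 to 0.07 for TGFBR1, -0.07 to 0.11 for TGFB1 and -0.07 to 0.1 for CCNE1.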

Other observations

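Neighbouring genes tended to change together between the lines. In the gene order of assembly GRCh38.p14, windows of 25 neighbouring genes with an absolute median log2 change above 0.15 joined into 40 stretches, 25 with a raised and 15 with a lowered median, which held 1663 genes. The longest, from ATP12A to OR7E156P, held 113 genes including RB1. Among its 40 brighter genes (mean log2 value of at least 8) 38 were lower in resistant cells, with a median log2 change of -0.302. The stretch from SDHA to TTC33, with DROSHA, had 30 of 33 brighter genes higher (median 0.347). That from HSPB3 to ARSB, with PIK3R1, had 26 of 28 lower (-0.321), that from ZNF141 to KIAA0232 had 24 of 25 lower (-0.343), and that from GRIN2B to PUS7L had 25 of 26 higher (0.283). In other stretches the brighter genes were mixed. The raised stretch from WASHC3 to TRPV4 had 9 lower and 10 higher, and that from ABCB6 to DOCK10 had 2 lower and 2 higher. A stretch of 26 genes from PGGHG to AP2A2 holds the interferon genes IFITM1, IFITM2, IFITM3 and IRF7. The named stretches were chosen after their values were seen, and since its own genes set the direction of a stretch, these counts describe the stretches and do not test them.

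Of the tests below, the one on leukocyte markers was written after that list's value was seen.

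The first pattern is this clustering. Windows of 25 neighbouring genes with an absolute median log2 change above 0.15 numbered 538 of 11378, against at most 44 in 100 shuffled gene orders, which argues against a chance order of genes. With 1 gene kept per symbol root, to remove families with shared sequence, there were 518 such windows, against at most 36. Among genes with a mean log2 value of at least 8 there were 873, against at most 79, which argues against dim genes near the floor. A difference in DNA copy number between the parental and resistant cells is a candidate explanation as a hypothesis; copy number was not measured here, and regional control of transcription stays open as well.

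The second pattern is the lower interferon response. Members measured by the 24 probe sets designed to match 1 gene had a median of -0.419, which argues against sequence shared between genes. Leaving out both arrays of any repeat number left the list's median at -0.586 to -0.419, which argues against a single pair as the source. The test on loss of leukocytes from the resistant culture cannot decide by itself. Their markers had a median log2 change of 0.008, but at a median log2 value of 5.25 in parental arrays they lay too near the floor to show a fall. T47D is an established breast cancer line, in which leukocytes could only be contaminants. An effect of the drug in the medium and a lasting change of the resistant cells cannot be told apart, since 0 resistant samples were grown without the drug.

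The third pattern is a difference between arrays of the same group in replication genes. The mean of the replication list deviated from its group mean by 0.079, 0.073 and -0.151 in parental repeats 1, 2 and 3, and by 0.039, 0.031 and -0.071 in the resistant ones. Its spread lay at percentile 100 of 1000 random lists matched on intensity in both groups, so it was larger than a shift common to genes of that intensity would give. The list's genes vary together (estimated correlation 0.611), while deviations of unrelated genes average out in random lists. The test therefore cannot argue against array-wide variation that acts on some genes more than others. For 3 of 3 repeat numbers the parental and resistant arrays deviated to the same side and in the same order. Repeat 3 was the low array in both groups, so these are not 3 independent agreements. A growth state shared by arrays of equal number would give this result. Any other source shared by them would give it too, and the test cannot tell these apart. The mitosis list deviated to the same sides but in another order. Its deviations were 0.018, 0.027 and -0.044 in parental repeats 1, 2 and 3 and 0.055, 0.053 and -0.108 in the resistant ones. The interferon list did not deviate to the same sides, with repeat 3 at 0.198 in parental and -0.205 in resistant cells.

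Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many calls, the real one, with 2551 genes and 223 changed by at least 1. The highest of the other splits gave 0 for both counts, including the other 3 that, like the real one, part all 3 pairs. With 10 splits a share under 0.05 cannot be reached.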
